A study of Ruditapes philippinarum with 68 samples.

How the data were processed

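Gene expression was measured in the digestive gland of the Manila clam, Ruditapes philippinarum, on 68 single-colour Agilent arrays of 15037 probes. Each array held RNA pooled from 5 clams, per the labels. The clams came from 2 places in the Venice lagoon, Chioggia and Marghera. They were sampled on arrival (wild, 6 pools per site), after 7 days in laboratory tanks (acclimated, 4 pools per site), and 1, 3 and 7 days later with or without copper at 50 µg per litre (4 pools per site, day and treatment). The 16 groups and the replicate numbers were taken from the sample titles. For the unexposed controls of days 3 and 7 another label field named day 1, and the titles were followed.

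The authors deposited a scanner file for each array together with a table of their own values. The scanner files hold spot intensity on a linear scale; per the file headers they came from Agilent Feature Extraction, which had subtracted the background, removed multiplicative trends within each array and replaced values that were not above background by a surrogate. The deposited files also hold the mean intensity of each spot and of its local background, together with flags for saturation, outliers and signal well above background. These intensity values were not normalized between arrays. The authors' table holds log2 values for 10469 of its 15573 features. The columns had medians between 5.97 and 6.04 and each correlated across probes with the log2 scanner values of its array at 0.959 or above, so the scale is log2 and genes were not centred on their means. The authors' normalization between arrays is not given in the sources used here.

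Control spots were left out, and the 167 spots with an outlier mark were set to missing. Each array was expressed as log2 of the processed signal minus its own 75th percentile, and all levels are given on this scale. Such a scale compares each probe with the bulk of its array, so a change shared by most probes would not be seen. Probes well above background on at least 4 arrays were kept, which left 10727. Limma (version 3.58.1, in R 4.3.3) was fitted with lmFit and eBayes over all 68 arrays with a coefficient for each of the 16 groups, so that all groups shared an estimate of the spread with 52 residual degrees of freedom. Every p-value for a probe is limma's two-sided value after Benjamini-Hochberg adjustment over the 10727 probes, and a probe was called where it was under 0.05. Standard errors (SE) come from the same fit. Effects averaged over days weight the 3 days equally. Where 2 lists of called probes are compared, the number expected for independent lists takes every probe as equally likely to be called. All lists of a fit rest on the same spread per probe, which favours probes of low spread in each. The expected numbers may therefore be too low. Tables were read with the data.table package (version 1.17.8) and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.

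The depth of an array is its signal over background. Between 44.1% and 66.0% of the probes were well above background on an array, with a median of 56.7%, and the number of arrays limits the precision. Where a probe was not well above background on any array of a group, only a bound is given: the brighter group's mean was set against the dim group's mean of the higher of the probe's own value and the lowest signal well above background on that array, and the result is written as at least N-fold. Arrays are separate pools of clams, but each site had 1 acclimation tank and the number of exposure aquaria is not given in the sources used here. The p-values therefore measure the spread between pools within a tank or aquarium.

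No probe had a gene description in the files, and none of the probe identifiers matched the supplied table of 48037 genes (assembly ASM2657151v2). Probes are therefore named by their identifiers, with the 60-base probe sequence for some of them. A list of 22 gene groups had been fixed before the data were examined, with 238 gene symbols, of which 0 occurred among the probe names; no group could be tested. The rule for the probes named here was also fixed before the data were examined. Without gene names it gives, in each comparison, at most 2 called probes with the largest rise and 2 with the largest fall. Further probes are named where a count of 5 or fewer was printed, and these were chosen after their values were seen.

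The arrays lay on 10 slides scanned on 6 days. Slide was tested as a batch, and 2750 of the 10727 probes differed between slides beyond the groups. The correlation between arrays of a slide, estimated by limma, was 0.179. The first principal component held 9.69% of the variance, and slide accounted for 67.0% of it while group accounted for 45.9%. Values are therefore also given with slide as a fixed block, and within the slides that held both sides of a comparison. Arrays of those slides also took part in choosing the probes, so a direction kept within a slide is no independent test. Of the 6 comparisons of copper with control on a single day, 5 shared no slide between the groups, and so did the acclimation change in Chioggia clams. In these the slide term rests on other groups. No pair of arrays correlated above 0.969, so none was treated as a repeat.

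Fixed before the data were examined were the alternatives of quantile normalization, a model-based background correction (normexp, offset 50, on the mean and local background signals), no filter on dim probes, the authors' values, slide as a fixed block, array weights, a trended robust variance model, fits on only the groups compared, the replicate number as a block, and leaving out each array in turn. Added after the data were seen were slide as a random block, centring within 6 bins of probe GC content, a filter requiring signal well above background on at least 34 arrays, the 75th percentile over only the probes detected on all arrays, 2 treatments of an array pair whose labels are in doubt, and leaving out 3 dim copper arrays of 1 slide. For each comparison the arrays were also regrouped into other splits of the same sizes, up to 100 of them. Means over sets of probes were compared by exact two-sided permutation tests, adjusted within each family.

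The fit was tested on simulated data in which 200 of 10727 probes were changed at each fold size. For the wild sites it recovered 25.5% of 1.5-fold, 61.5% of 2-fold and 96.5% of 4-fold changes, and 3.67% of its calls were false. For acclimation in Chioggia clams it recovered 26.0%, 58.5% and 91.5%, with 5.12% false. For copper at day 7 in Marghera clams it recovered 16.0%, 50.0% and 87.0%, with 5.26% false. For copper averaged over days in Chioggia clams it recovered 50.0%, 79.0% and 98.5%, with 4.61% false. The simulated data held no slide effect.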

Results

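Expression was measured in the digestive gland, the organ of food digestion and metal storage in bivalves, of Manila clams from Chioggia and Marghera in the Venice lagoon. The 68 arrays comprised 6 pools of wild clams per site, 4 pools per site after 7 days of acclimation, and 4 pools per site, day and treatment after 1, 3 and 7 further days with or without 50 µg per litre of copper. Each pool held 5 clams. Between 44.1% and 66.0% of the probes were well above background on an array, and at most 1 probe per array was saturated. The mean share per group ran from 50.3% ± 6.93 (SD, n = 4) in the Marghera copper arrays of day 3 to 62.8% ± 2.29 (SD, n = 4) in acclimated Marghera clams. Probes are identified by the array design only, since the files gave no gene names. All levels are log2 signal relative to the 75th percentile of the array.

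The first comparison asked how wild clams from the 2 sites differed. RP_ill_contig_233447 (probe sequence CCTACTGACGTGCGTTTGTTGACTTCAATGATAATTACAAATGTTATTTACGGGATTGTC) was higher in Marghera, at -0.83 ± 0.61 against -3.93 ± 0.90 in Chioggia (SD, n = 6 each), where 1 of 6 arrays was well above background. The difference was 3.10 ± 0.52 on the log2 scale (SE, adjusted p = 0.00033). Probe ruditapesP_lrc34953_1 (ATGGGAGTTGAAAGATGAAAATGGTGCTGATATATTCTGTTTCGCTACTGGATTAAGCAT) was lower in Marghera by a log2 difference of -3.53 ± 0.69 (SE, adjusted p = 0.00147), with a level of 4.83 ± 0.46 in Chioggia (SD, n = 6). Probe ruditapesN_lrc32645 (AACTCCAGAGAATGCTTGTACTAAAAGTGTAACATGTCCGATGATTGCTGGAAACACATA) was lower by -2.94 ± 0.58 (SE, adjusted p = 0.00193) and stood at 3.94 ± 0.23 in Chioggia (SD, n = 6). Probe ruditapes_lrc35964_S was higher in Marghera by 3.03 ± 0.93 (SE, adjusted p = 0.0488). Without any single array other than Chioggia replicate 2 or Marghera replicate 3 that last call was lost, with adjusted p up to 0.157, and it was lost with slide as a fixed block, at 3.29 ± 1.12 (SE).

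In all, 417 probes differed between the wild clams, 258 higher and 159 lower in Marghera, with a median absolute log2 difference of 0.80. The balance of directions depended on the scaling. It was 159 higher and 191 lower with quantile normalization, 198 and 193 with the authors' values, and 210 and 237 when the percentile was taken over probes detected on all arrays. Slide 1 held 3 Marghera and 4 Chioggia wild arrays, and within it all 417 probes kept their direction, at a median log2 difference of 0.71. These arrays also helped choose the probes, so that is no independent test, and 9 probes were called from that slide alone. A fixed slide block called 187 probes, 96 higher and 91 lower, and a fit of only the wild groups called 73. The normexp background called 6, and it ended the calls of all 4 probes named above. The count fell to 116 without Marghera replicate 5, to 201 without Chioggia replicate 1 and to 260 without Chioggia replicate 4.

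After acclimation only 2 probes were called between the sites, both lower in Marghera. RP_ill_contig_99200 stood at -2.88 ± 0.77 in Marghera and -0.53 ± 0.86 in Chioggia (SD, n = 4 each), a difference of -2.35 ± 0.46 (SE, adjusted p = 0.024). RP_ill_contig_187828 stood at -0.81 ± 0.70 and 1.09 ± 0.72 (SD, n = 4 each), a difference of -1.90 ± 0.36 (SE, adjusted p = 0.024). Both kept their direction within each of the 3 slides that held both sites, at a median log2 difference between 1.26 and 2.28. At an unadjusted p under 0.05 limma gave 709 probes, against 536 expected by chance. A fixed slide block called 0 probes in limma, with 869 at an unadjusted p under 0.05, as the differences went to -2.21 ± 0.49 and -1.72 ± 0.36 (SE). Both calls were lost without Chioggia replicate 1, 2 or 3 or Marghera replicate 3 or 4, which left 0 probes in limma with 505 to 675 at an unadjusted p under 0.05, while 6 were called without Chioggia replicate 4 and 4 without Marghera replicate 1 or 2.

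The unexposed controls, kept up to 14 days in the laboratory, were compared between sites over the 3 days together. The same 3 probes as in wild clams were among the largest differences. Probe ruditapesN_lrc32645 stood at 0.82 ± 0.94 in Marghera and 4.06 ± 1.19 in Chioggia (SD, n = 12 each), a difference of -3.24 ± 0.41 (SE, adjusted p = 5.82e-07). Probe ruditapesP_lrc34953_1 was lower in Marghera by -2.95 ± 0.49 (SE, adjusted p = 0.000117). RP_ill_contig_233447 was higher by 1.92 ± 0.37 (SE, adjusted p = 0.000916), a call lost with slide as a fixed block, where the difference was 2.06 ± 0.62 (SE). RP_ill_contig_190621 was higher by 1.84 ± 0.39 (SE, adjusted p = 0.00237). On the acclimated arrays the same differences were -2.82 for ruditapesN_lrc32645 (adjusted p = 0.17), -2.47 for ruditapesP_lrc34953_1 (adjusted p = 0.42) and 1.55 for RP_ill_contig_233447 (adjusted p = 0.60), none of which passed the test.

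**Figure D1:**
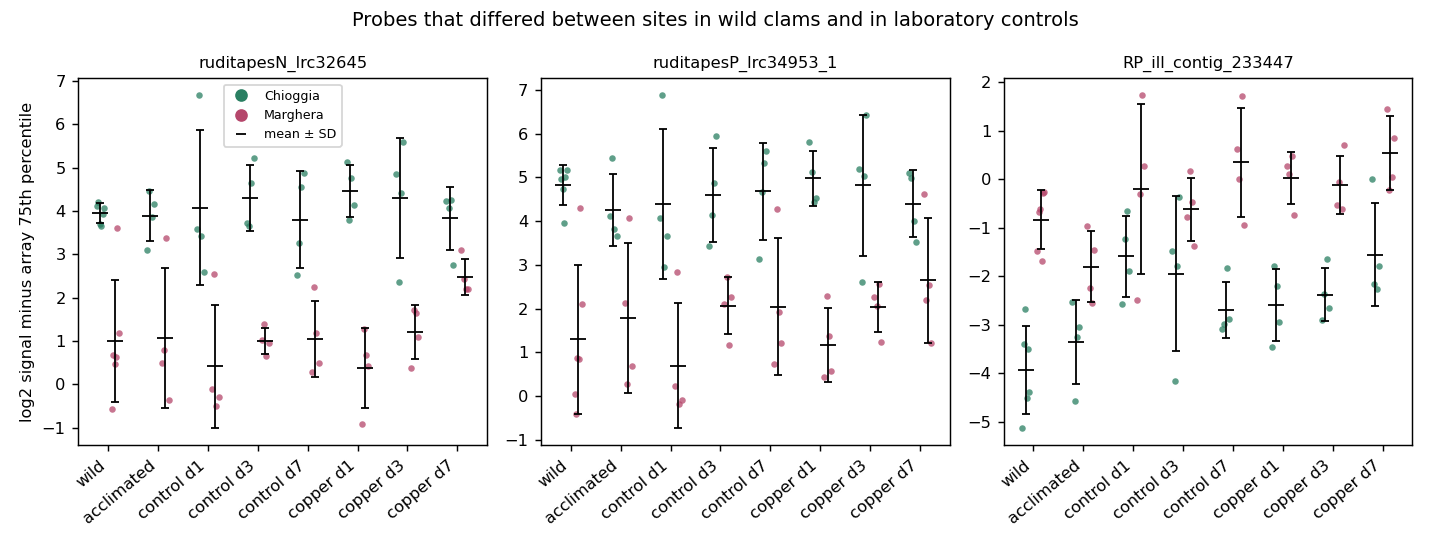
Levels of 3 probes that differed between sites both in wild clams and in controls, as log2 signal minus the 75th percentile of the array, by stage and site, with a point for each array and bars for the mean ± SD. For ruditapesN_lrc32645 the wild Chioggia arrays averaged 3.94 and the wild Marghera arrays 1.00.

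In the controls 503 probes differed between sites, 241 higher and 262 lower in Marghera, and 368 higher and 210 lower when the percentile was taken over probes detected on all arrays. Of the 417 probes of the wild comparison, 42 were called here in the same direction, against 9.68 expected for independent lists, and 5 in the opposite direction. Of all 417, 48.0% had the same direction in the controls and 66.7% on the acclimated arrays, against 45.7% and 53.0% of all tested probes, and the r across probes with the controls was 0.0269. Those 5, named after their values were seen, were RP_ill_contig_23461, RP_ill_contig_204269, ruditapesP_lrc39924 and RP_ill_contig_204778, higher in wild Marghera clams, and RP_ill_contig_279607, lower there by -0.86 ± 0.22 (SE, adjusted p = 0.0178). A fixed slide block gave 241 probes, 22 of them shared with the wild comparison in direction and 0 opposite, and 72.7% of its 187 wild calls had the same direction in the controls. The normexp background gave 50, 16 higher and 34 lower. On slide 10, with 3 arrays per site taken on differing days, 94.0% of the 503 probes kept their direction. Without the Chioggia control of day 1 replicate 2 the count was 333.

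Acclimation was described by setting acclimated against wild clams of the same site. In Chioggia clams RP_ill_contig_240531 (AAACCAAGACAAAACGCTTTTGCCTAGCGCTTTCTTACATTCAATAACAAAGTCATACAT) rose from -3.95 ± 0.61 (SD, n = 6, well above background on 2 arrays) to -1.54 ± 0.68 (SD, n = 4), by 2.41 ± 0.44 (SE, adjusted p = 0.000269). RP_ill_contig_122132_AS was at least 1.59-fold higher after acclimation (adjusted p = 0.03), as it was not well above background on any wild array. RP_ill_contig_164013 changed by -3.40 ± 0.88 (SE, adjusted p = 0.0151) and RP_ill_contig_279426 by -2.76 ± 0.84 (SE, adjusted p = 0.0448), with 1 and 2 of the 4 acclimated arrays well above background. The calls were lost for RP_ill_contig_164013 without acclimated replicate 2 or 3, and for RP_ill_contig_122132_AS without wild replicate 2 or 5 or acclimated replicate 1, 2 or 4. That of RP_ill_contig_279426 was lost without any array but wild replicate 5 and acclimated replicate 3, with adjusted p up to 0.188. With the normexp background RP_ill_contig_122132_AS turned direction. Under the fixed slide block none of the 4 calls was kept, at 2.51 ± 0.64 for RP_ill_contig_240531, -0.70 ± 0.96 for RP_ill_contig_164013 and -2.96 ± 1.32 for RP_ill_contig_279426 (SE).

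In Chioggia clams 478 probes changed, 285 up and 193 down, or 216 up and 267 down when the percentile was taken over probes detected on all arrays. Wild and acclimated Chioggia arrays shared no slide. A fixed slide block, which here rests on other groups, called 48 probes, 36 up and 12 down, and 43 of them were among the 478, while a fit of only the groups compared called 150. The count was 271 without acclimated replicate 2, 291 without acclimated replicate 3 and 317 without wild replicate 3.

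In Marghera clams RP_ill_contig_166598 (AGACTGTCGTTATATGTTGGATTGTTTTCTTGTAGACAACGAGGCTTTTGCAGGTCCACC) fell from 1.34 ± 0.32 (SD, n = 6) to -1.71 ± 0.54 (SD, n = 4), a change of -3.05 ± 0.59 (SE, adjusted p = 0.000472). In Chioggia clams the same probe changed by -2.18 (adjusted p = 0.021). RP_ill_contig_232540 was at least 11.7-fold lower after acclimation (adjusted p = 0.0166), as it was well above background on 5 of 6 wild and 0 of 4 acclimated arrays. RP_ill_contig_164955 was at least 2.51-fold higher (adjusted p = 0.0159), and RP_ill_contig_110875_AS rose by 2.81 ± 0.74 (SE, adjusted p = 0.0108), with 3 of 4 acclimated and 1 of 6 wild arrays well above background. Both of these calls were lost without acclimated replicate 3 or 4, with adjusted p up to 0.0737. That of RP_ill_contig_110875_AS was also lost with slide as a fixed block, at 2.49 ± 0.86 (SE), and that of RP_ill_contig_232540 with quantile normalization.

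In Marghera clams 790 probes changed, 362 up and 428 down. The balance of directions depended on the processing, with 398 up and 322 down with quantile normalization and 473 up and 1899 down without a filter on dim probes. A fit of only the groups compared called 217. Within slides 2 and 5, which held both groups and arrays that helped choose the probes, 99.1% and 96.8% of the 790 probes kept their direction. With slide as a fixed block 955 probes were called, 570 of them among the 790. The count was 450 without acclimated replicate 3 and 490 without acclimated replicate 4. Between the sites 168 probes changed in the same direction, 91 up and 77 down, where independent lists would share 17.3, and 0 changed in opposite directions. Under the fixed slide block the 2 lists shared 31 probes against 2.06 expected.

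**Figure D2:**
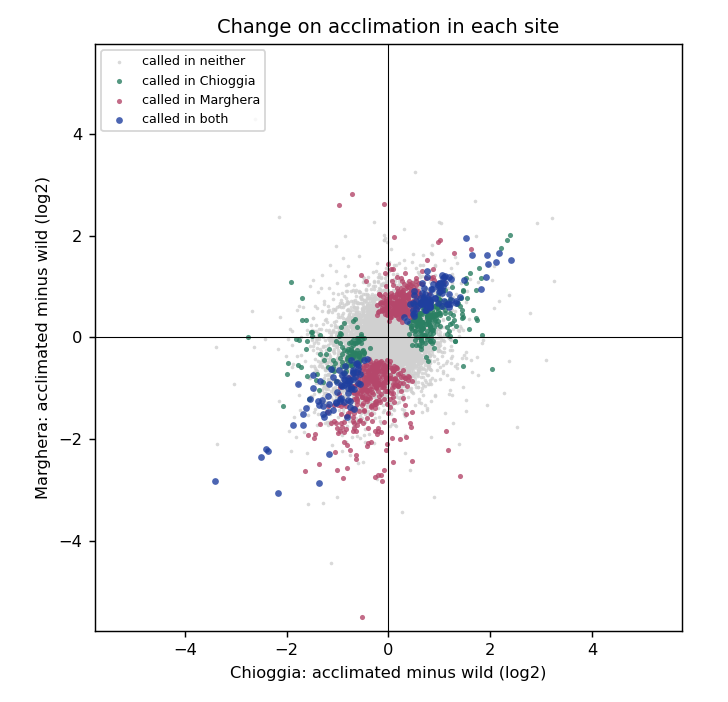
Log2 change from wild to acclimated clams in Chioggia (horizontal) and Marghera (vertical), with a point for each of 10727 probes. The 168 probes called in both sites lie in the quadrants of equal sign.

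The difference between the acclimation changes of the 2 sites was tested as an interaction. RP_ill_contig_872 rose in Marghera by 0.71 (adjusted p = 4.1e-05) and moved by -0.05 in Chioggia (adjusted p = 0.86), an interaction of 0.77 ± 0.17 (SE, adjusted p = 0.0472). Probe ruditapesP_c11429_1 fell in Marghera, by -1.46 (adjusted p = 0.00039) against 0.47 in Chioggia (adjusted p = 0.36), an interaction of -1.93 ± 0.39. RP_ill_contig_39925 changed by -2.22 in Marghera and 1.17 in Chioggia, an interaction of -3.39 ± 0.72, and RP_ill_contig_34031 by 0.33 and -0.70, an interaction of 1.03 ± 0.22. With RP_ill_contig_22878 (-1.33 ± 0.27), named after its value was seen, these were the 5 probes called, each at adjusted p = 0.0472, 2 higher and 3 lower. At an unadjusted p under 0.05 limma gave 1172 probes, and with slide as a fixed block it called 0, with 1237 at an unadjusted p under 0.05. The normexp background also gave 0, with 497. With the block the interactions of the 4 probes named first were 0.74 ± 0.15, -1.86 ± 0.41, -3.29 ± 0.77 and 0.94 ± 0.23 (SE). Without any single array other than wild Chioggia replicate 3 or wild Marghera replicate 2 the count moved to between 0 and 3, and the named calls were lost in most of those fits, with adjusted p up to 0.233. The 10 fits with 0 calls left out wild Chioggia replicate 1, 2, 4 or 6, acclimated Chioggia replicate 2 or 4, or wild Marghera replicate 1, 3, 5 or 6, with 842 to 1185 probes at an unadjusted p under 0.05.

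Copper was compared with the unexposed controls of the same site and day. After 1 day few probes differed. In Chioggia clams RP_ill_contig_110697 (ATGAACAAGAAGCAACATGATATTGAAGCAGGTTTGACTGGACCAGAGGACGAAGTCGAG) was lower with copper, at -3.30 ± 0.26 against -1.22 ± 1.15 (SD, n = 4 each), by -2.08 ± 0.31 (SE, adjusted p = 9.35e-05), and it was the 1 probe called. The call was lost with slide as a fixed block, where the difference was -1.52 ± 0.42 (SE) and limma called 0 probes with 777 at an unadjusted p under 0.05. In Marghera clams ruditapesP_lrc33491 (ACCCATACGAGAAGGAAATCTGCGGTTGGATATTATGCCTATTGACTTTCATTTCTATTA) was higher with copper by 6.03 ± 0.80 (SE, adjusted p = 5.84e-06), at 1.26 ± 3.35 against -4.77 ± 0.89 (SD, n = 4 each), with 1 control array well above background. The copper arrays of ruditapesP_lrc33491 ran from -3.40 to 3.77, and its highest control stood at -3.54. Its SE and p rest on the spread pooled over all groups, these copper pools included, and not on that of the copper pools alone. The probe was well above background on 15 of the 68 arrays. RP_ill_contig_24461 was higher by 2.66 ± 0.51 (SE, adjusted p = 0.0158), and its call was lost without control replicate 1 or 4 or copper replicate 4 or 5. In Marghera clams limma called 0 probes with slide as a fixed block, with 1076 at an unadjusted p under 0.05, and the 2 differences were then 5.49 ± 1.34 and 3.48 ± 0.77 (SE). A fit of only the groups compared called 0 in either site, with 391 and 686 in limma at an unadjusted p under 0.05, and the normexp background called 0 in Chioggia, with 263. At this day the groups shared no slide in either site.

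These counts of 1 and 2 moved with single arrays. In Chioggia clams 2 probes were called without control replicate 1 or 5 or copper replicate 1 or 5, 3 without control replicate 2 and 4 without control replicate 4. In Marghera clams 1 was called without control replicate 1 or 4, 5 without control replicate 2 or copper replicate 2 or 5, and 9 without copper replicate 4. The Chioggia copper arrays of day 1 replicate 5 and day 3 replicate 5 correlated with each other's column in the authors' table, at 0.993 and 0.990 over probes centred on their means, and not with their own, at 0.010 and 0.023. Which of the 2 sources has them right could not be told, and they were analysed here as the scanner files label them.

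After 3 days of copper RP_ill_contig_42186 and RP_ill_contig_771 were at least 2.40-fold and at least 2.26-fold higher in Chioggia clams (adjusted p = 0.00265 and 0.0111), as neither was well above background on any Chioggia control array of that day, and 3 and 2 of 4 copper arrays showed them above it. Without copper they were well above background on 2 and 1 of 4 Marghera controls of day 3, and RP_ill_contig_42186 also on 1 wild Chioggia array. Probe ruditapesP_c8136 (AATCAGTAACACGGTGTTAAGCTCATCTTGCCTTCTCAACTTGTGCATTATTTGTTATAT) was lower by -3.08 ± 0.81 (SE, adjusted p = 0.0437), and RP_ill_contig_221441 was at least 1.40-fold lower (adjusted p = 0.0434). RP_ill_contig_247878 and RP_ill_contig_179448_S, named after their values were seen, were lower by -0.64 ± 0.16 and -1.56 ± 0.40 (SE, adjusted p = 0.0261 and 0.0427). In all 86 probes were called, 82 higher and 4 lower. The split was 63 and 18 with quantile normalization and 100 and 29 with the authors' values. The typical called probe was dim, well above background on 10.3% of the 68 arrays. Control and copper arrays shared no slide, and with slide as a fixed block limma called 0 probes, with 729 at an unadjusted p under 0.05, as the fitted rises of RP_ill_contig_42186 and RP_ill_contig_771 shrank, the former to below its bound, while ruditapesP_c8136 stood at -3.25 ± 1.31 (SE). A fit of only the groups compared called 1 probe, and the normexp background called 0, with 268 in limma at an unadjusted p under 0.05.

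At day 3 in Chioggia the count was 10 without copper replicate 1 or 2, 18 without copper replicate 4, 14 without control replicate 4, 44 and 48 without control replicates 2 and 1, and 284 without copper replicate 5, the array whose label is in doubt. With the doubted pair exchanged it was 205, and without both arrays 292. The call of RP_ill_contig_771 was lost without control replicate 4 or copper replicate 1 or 4. That of ruditapesP_c8136 was lost without any array but control replicate 1 and copper replicate 5, and that of RP_ill_contig_221441 without any but copper replicate 4, with adjusted p up to 0.262 and 0.298.

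In Marghera clams at day 3 RP_ill_contig_142288 was higher with copper by 2.43 ± 0.57 (SE, adjusted p = 0.0225), at -0.13 ± 1.75 against -2.56 ± 0.55 (SD, n = 4 each). RP_ill_contig_38255 was at least 2.89-fold higher (adjusted p = 0.0484), well above background on 3 copper and 0 control arrays. RP_ill_contig_241398 and RP_ill_contig_41977 were at least 2.17-fold and at least 1.34-fold lower (adjusted p = 0.0497 and 0.0389), well above background on 0 copper arrays each. In Chioggia at day 3 RP_ill_contig_241398 was well above background on 3 of 4 copper and 0 of 4 control arrays. In all 82 probes were called in Marghera, 43 higher and 39 lower, or 39 and 89 when the percentile was taken over probes detected on all arrays, a choice that shifted the median of all probes to -0.13. No probe was shared with the Chioggia calls of that day, where independent lists would share 0.343, and the r across probes was -0.0876. On slide 7, with 1 copper and 2 control arrays, 81.7% of the 82 probes kept their direction. With slide as a fixed block limma called 0, with 790 at an unadjusted p under 0.05, and RP_ill_contig_142288 went to 0.79 ± 0.63 (SE). The fitted changes of RP_ill_contig_38255 and RP_ill_contig_41977 also shrank, while that of RP_ill_contig_241398 did not and its SE rose. A fit of only the groups compared called 1 probe, and the normexp background 22, all higher.

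Copper replicates 2, 4 and 5 of this group, all on slide 8, had 48.6%, 44.1% and 48.1% of the probes well above background, against 60.2% for replicate 1 and 56.3% to 63.9% for the controls. Without these 3 arrays, in a fit that assumes the remaining array to vary like the other groups, 6 probes were called, RP_ill_contig_38255 and RP_ill_contig_142288 turned direction, and the other named calls were lost.

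At day 3 in Marghera the count was 2, 3 and 25 without copper replicates 5, 4 and 2, and 216 without copper replicate 1. It was 27, 26 and 9 without control replicates 1, 2 and 4. The calls of the named probes were lost in most of these fits. RP_ill_contig_38255 kept its call only without copper replicate 1, RP_ill_contig_142288 without copper replicate 1 or control replicate 2, RP_ill_contig_41977 without copper replicate 1 or control replicate 2, and RP_ill_contig_241398 in none of the 8, with adjusted p up to 0.290.

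After 7 days of copper ruditapesP2_c3094_1 (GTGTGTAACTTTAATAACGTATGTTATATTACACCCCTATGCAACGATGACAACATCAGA) was higher in both sites. It was at least 3.61-fold higher in Chioggia (adjusted p = 0.011) and at least 6.19-fold higher in Marghera (adjusted p = 0.00641), with 0 of 4 control and 4 of 4 copper arrays well above background in each. Without copper it was also well above background on 4 of 4 acclimated Marghera arrays and 1 of 4 acclimated Chioggia arrays. The same held for 1 of 4 controls of each site at days 1 and 3, and for 0 wild arrays. Probe ruditapesP_c8136 was lower in both, by -3.94 ± 0.81 in Chioggia (SE, adjusted p = 0.00549) and by -2.91 ± 0.81 in Marghera (SE, adjusted p = 0.0369). In each site 1 of 4 copper and 4 of 4 control arrays showed it well above background. RP_ill_contig_17282 (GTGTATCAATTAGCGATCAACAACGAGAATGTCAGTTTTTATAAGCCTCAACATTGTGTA) was higher in Marghera, at 0.90 ± 1.23 against -2.56 ± 0.49 (SD, n = 4 each), by 3.46 ± 0.76 (SE, adjusted p = 0.00518), and differed by 2.37 in Chioggia (adjusted p = 0.13). RP_ill_contig_192258 was higher in Chioggia by 2.94 ± 0.75 (SE, adjusted p = 0.0349), and by 5.81 ± 1.32 (SE) with slide as a fixed block. Its call was lost with slide as a random block, without a filter on dim probes, with the normexp background and in a fit of only the groups compared. Probe ruditapesP_c737 was lower there by -7.43 ± 1.99 (SE, adjusted p = 0.0468), with 2 of 4 copper and 4 of 4 control arrays well above background. Without copper it was also patchy, on 2 of 4 Marghera controls at days 1 and 7. RP_ill_contig_34464 was at least 2.49-fold lower in Marghera (adjusted p = 0.0322).

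At day 7 copper changed 103 probes in Chioggia clams, 64 higher and 39 lower, and 251 in Marghera clams, 144 higher and 107 lower. The Marghera split was 89 and 207 when the percentile was taken over probes detected on all arrays, with the median of all probes at -0.13. The sites shared 30 probes in the same direction, 24 higher and 6 lower, where independent lists would share 1.25. Both lists rest on the same spread per probe, so that expected number may be too low. RP_ill_contig_80412_S was called in opposite directions, higher by 1.70 ± 0.43 in Chioggia and at least 2.05-fold lower in Marghera, where it was well above background on 0 of 4 copper arrays, and is named after its values were seen. Over all probes the r between the sites was 0.152. Copper and control arrays of this day shared no slide in either site. A fixed slide block called 53 and 52 probes, sharing 2 against 0.154 expected, and it ended the calls of ruditapesP2_c3094_1 and ruditapesP_c8136 in both sites, of ruditapesP_c737 in Chioggia, and of RP_ill_contig_17282 and RP_ill_contig_34464 in Marghera. For ruditapesP_c8136 the differences were then -4.67 ± 1.56 and -3.64 ± 1.26, for ruditapesP_c737 -12.05 ± 3.59 and for RP_ill_contig_17282 2.41 ± 1.16 (SE). A fit of only the groups compared called 12 probes in Chioggia and 0 in Marghera, with 1413 there in limma at an unadjusted p under 0.05, and the normexp background called 9 and 48.

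**Figure D3:**
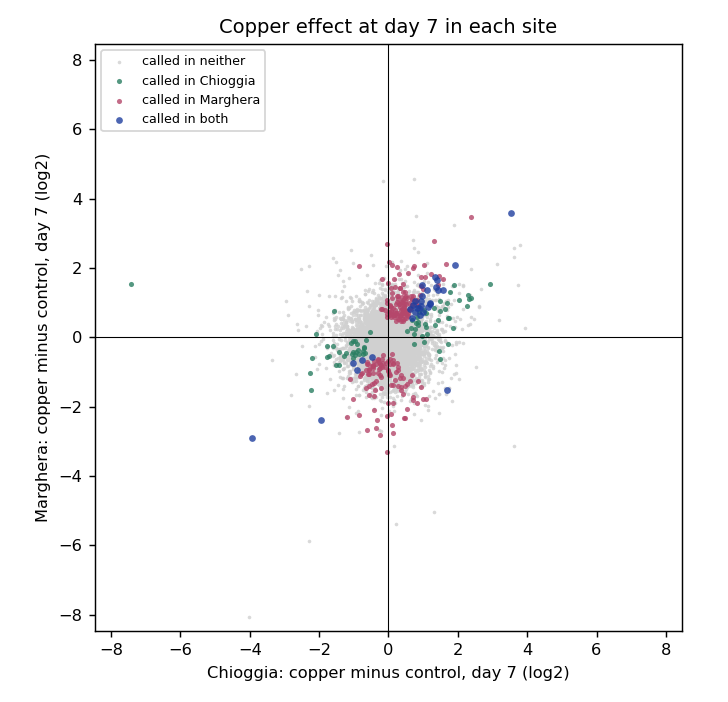
Log2 difference between copper and control at day 7 in Chioggia (horizontal) and Marghera (vertical), with a point for each of 10727 probes. Of the probes called in both sites, 30 lie in the quadrants of equal sign and 1 in a quadrant of opposite sign.

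At day 7 in Chioggia the count was 60, 65 and 60 without control replicates 1, 2 and 4 and 58 without copper replicate 5. In Marghera it was 121 without control replicate 1 and 120, 161 and 167 without copper replicates 1, 2 and 4. Several named calls lay close to the threshold. That of ruditapesP_c737 was lost without any of the 8 arrays (adjusted p up to 0.137), though its difference stayed between -7.81 and -6.92, and that of RP_ill_contig_192258 without any but control replicate 1 and copper replicate 4 (up to 0.157), with differences between 2.46 and 2.98 where it was lost. In Marghera those of ruditapesP_c8136 and RP_ill_contig_34464 were lost without any array but copper replicate 5 for the former and control replicates 1 and 5 for the latter, with adjusted p up to 0.126 and 0.120.

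Averaged over the 3 days, RP_ill_contig_1750 (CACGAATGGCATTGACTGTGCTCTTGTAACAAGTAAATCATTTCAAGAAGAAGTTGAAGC) was higher with copper in Chioggia clams, at 0.87 ± 0.53 against -0.59 ± 0.41 (SD, n = 12 each), by 1.47 ± 0.19 (SE, adjusted p = 5.29e-06). It was 0.80, 1.35 and 2.26 higher at days 1, 3 and 7, and 0.73 higher on average in Marghera clams (adjusted p = 0.022). Probe ruditapesP_c8136 was lower by -2.35 ± 0.47 in Chioggia (SE, adjusted p = 0.00255) and by -1.98 ± 0.47 in Marghera (SE, adjusted p = 0.00847). RP_ill_contig_202244 was lower in Chioggia by -1.64 ± 0.24 (SE, adjusted p = 6.69e-05), and RP_ill_contig_153407 was at least 1.10-fold higher (adjusted p = 0.00431), well above background on 5 of 12 copper arrays. Both calls were lost with the normexp background, and that of RP_ill_contig_153407 also in a fit of only the groups compared.

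In Marghera clams RP_ill_contig_3019 (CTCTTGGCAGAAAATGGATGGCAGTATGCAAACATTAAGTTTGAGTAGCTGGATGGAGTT) was lower with copper on average, at -0.54 ± 0.54 against 1.03 ± 0.96 (SD, n = 12 each), by -1.56 ± 0.19 (SE, adjusted p = 2.01e-07). The difference was -1.16, -1.14 and -2.38 at days 1, 3 and 7, and -1.03 on average in Chioggia clams (adjusted p = 0.00097). On acclimation the same probe had changed by -2.37 in Chioggia (adjusted p = 1.8e-07) and -2.24 in Marghera (adjusted p = 1.8e-06). Its copper call held under all 15 alternatives, among them slide as a fixed block. Probe ruditapesP2_c3094_1 was higher by 2.49 ± 0.46 (SE, adjusted p = 0.000647) and RP_ill_contig_17282 by 2.34 ± 0.44 (SE, adjusted p = 0.000681), and both kept their calls with slide as a fixed block, whereas ruditapesP_c8136 lost its call there, at -1.86 ± 0.58 (SE).

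On average 115 probes responded in Chioggia, 79 higher and 36 lower, and 330 in Marghera, 196 higher and 134 lower. The Marghera split was 115 and 118 with quantile normalization, and 130 and 344 when the percentile was taken over probes detected on all arrays, which put the median of all probes at -0.12. The sites shared 38 probes, all in the same direction, where independent lists would share 1.89. Under the fixed slide block 47 and 270 probes were called and 16 were shared against 0.58 expected, while the normexp background called 25 and 19. Within slides 6 and 10, 99.1% and 89.6% of the Chioggia probes kept their direction, and within slides 7, 8 and 9, 90.9%, 79.7% and 98.5% of the Marghera probes, where slide 7 compares arrays of day 3 and the other 4 slides compare different days. The count was 208 in Chioggia without copper day 3 replicate 5, the array in doubt, and 197 in Marghera without control day 7 replicate 1. Without the 3 dim Marghera copper arrays of day 3 it was 100, 59 higher and 41 lower, and ruditapesP_c8136 lost its call.

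**Figure D4:**
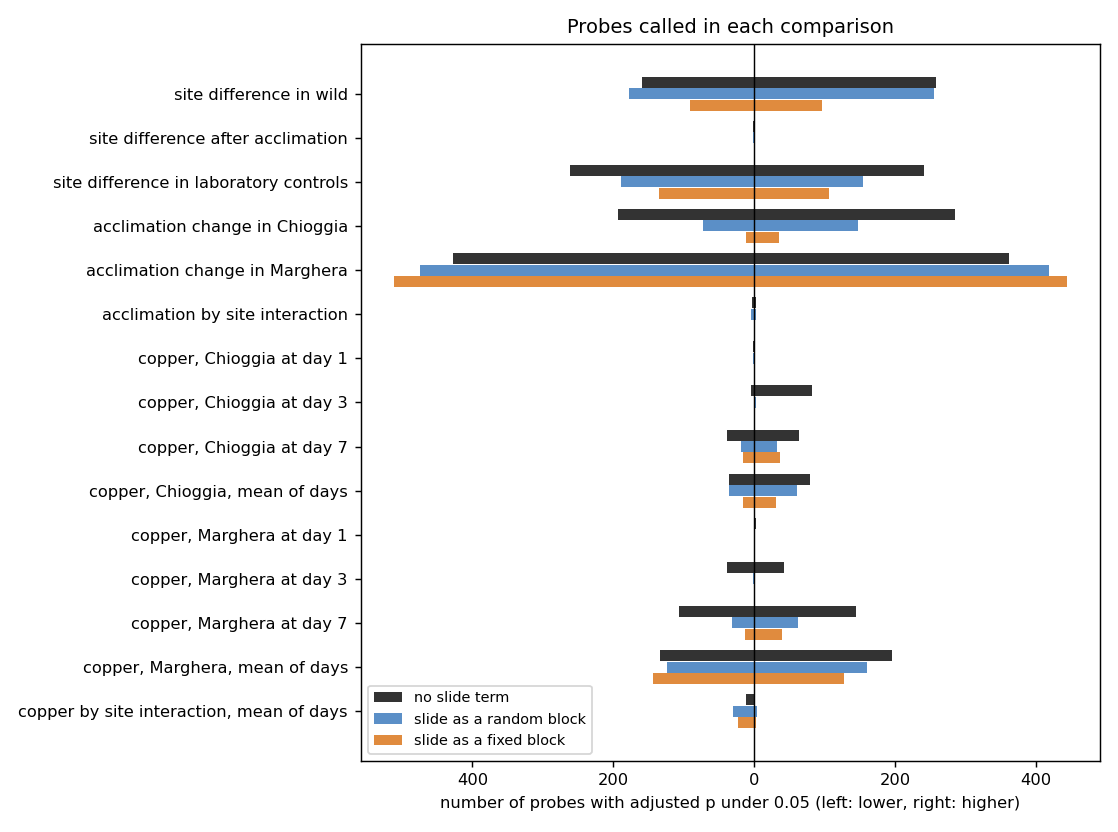
Number of probes called in each comparison (adjusted p under 0.05), lower to the left and higher to the right, without a slide term and with slide as a random or a fixed block. The fixed block lowered the count for acclimation in Chioggia from 478 to 48 and raised the count for Marghera from 790 to 955.

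Whether the averaged copper effect differed between sites was tested as an interaction. RP_ill_contig_33484 was called (adjusted p = 0.000706), but no fold can be given, since it was well above background on 2 of 12 copper and 0 of 12 control arrays in Chioggia and on 0 of 12 copper and 2 of 12 control arrays in Marghera, and its direction turned with the normexp background. RP_ill_contig_264441 differed by 1.23 in Chioggia (adjusted p = 0.017) and -0.73 in Marghera (adjusted p = 0.16), an interaction of -1.96 ± 0.42 (SE, adjusted p = 0.0256). In all 11 probes were called, all of them lower, 26 with slide as a fixed block, 2 without the 3 dim Marghera copper arrays of day 3, and 0 with the normexp background, with 1208 in limma at an unadjusted p under 0.05. The call of RP_ill_contig_264441 was lost without those 3 arrays, and also without the Chioggia control of day 1 replicate 4 or day 7 replicate 2, Chioggia copper day 7 replicate 4 or the Marghera control of day 3 replicate 1, with adjusted p up to 0.0542.

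Day by day the same interaction called 2 probes at day 1, 131 at day 3 (18 higher and 113 lower) and 4 at day 7. Both probes of day 1, named after their values were seen, were higher in Marghera, ruditapesP_lrc33491 by 5.76 ± 1.13 (SE) and RP_ill_contig_281164, each at adjusted p = 0.0372. With copper the latter was at least 1.66-fold higher in Marghera and at least 5.82-fold lower in Chioggia, on 3 of 4 arrays of the brighter group in each. Neither of these differences was called within its site, and the probe was well above background on 13 of the 68 arrays. The 4 of day 7, named likewise, were RP_ill_contig_2309 (-1.75 ± 0.34), RP_ill_contig_282719 (-2.42 ± 0.50), RP_ill_contig_33369 (-2.80 ± 0.59) and RP_ill_contig_80412_S (adjusted p = 0.0218). Without the 3 dim Marghera copper arrays the count of day 3 was 24. A fixed slide block called 0, 0 and 6 probes, with 487 and 750 at an unadjusted p under 0.05 in limma at days 1 and 3.

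The averaged interaction count was 93 without Chioggia copper day 3 replicate 5, the array in doubt. Without a Chioggia control it was 5 (day 1 replicate 4), 19 (day 1 replicate 5), 7 (day 3 replicate 4), 30 (day 3 replicate 5) or 7 (day 7 replicate 2). Without a Chioggia copper array it was 23 (day 1 replicate 4), 7 (day 3 replicate 4) or 4 (day 7 replicate 4). Without a Marghera control it was 5 (day 3 replicate 1) or 6 (day 7 replicate 1), and without a Marghera copper array 21 (day 1 replicate 4), 7 (day 7 replicate 2) or 22 (day 7 replicate 4).

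The 30 probes called at day 7 in both sites were followed through all groups as a mean deviation, signed by the direction of the copper effect. It was -0.64 ± 0.21 in wild Chioggia and -0.55 ± 0.19 in wild Marghera clams (SD, n = 6 each), and 0.02 ± 0.06 and 0.04 ± 0.16 after acclimation (SD, n = 4 each). At day 7 the controls stood at -0.43 ± 0.08 and -0.44 ± 0.15, and the copper arrays at 0.81 ± 0.20 and 0.81 ± 0.17 (SD, n = 4 each). The probes were chosen on the day 7 arrays, so that difference is not a test. Under the fixed slide block all 30 kept their direction in both sites.

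**Figure D5:**
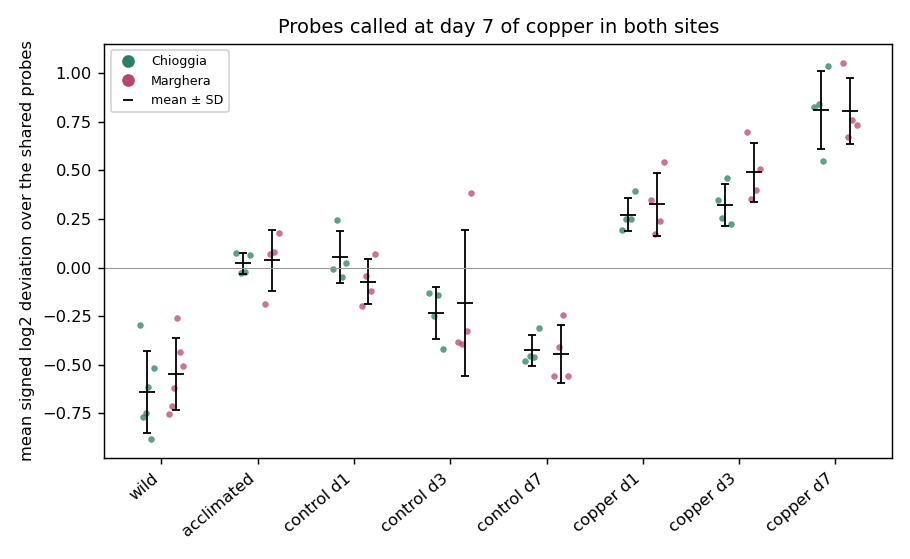
Mean over the 30 probes called at day 7 of copper in both sites, signed by the copper effect, in log2 units, by stage and site, with a point for each array and bars for the mean ± SD. The day 7 copper arrays average 0.81 in both sites and the day 7 controls -0.43 in Chioggia and -0.44 in Marghera.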

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

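Of the tests here, those of slide and of copper acting alike in both sites for the day 3 probes, that of the doubted pair, and those of slide 9, of continued acclimation and of copper at days 1 and 3 for the day 7 probes were chosen only after the result was seen.

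Single arrays stood apart from their group for 11 named probes and 1 quality measure, where chance would give 4.9 of the 98 groups tested. For ruditapesP_lrc34953_1 wild Chioggia replicate 4 stood at 3.96, below the next at 4.73. For RP_ill_contig_240531 wild Chioggia replicate 3 stood at -5.14, below the next at -3.85. For RP_ill_contig_110875_AS acclimated Marghera replicate 1 stood at -4.43, below the next at -1.30. For RP_ill_contig_232540 wild Marghera replicate 4 stood at -4.94, below the next at -1.14. For ruditapesP_c11429_1 acclimated Marghera replicate 4 stood at -1.23, below the next at 0.31. In the Chioggia copper arrays of day 3, RP_ill_contig_42186 stood at -4.51 on replicate 5, below the next at -1.85, and this array is 1 of the doubted pair. In the Chioggia controls of day 3, RP_ill_contig_771 stood at -4.77 on replicate 5, above the next at -5.60, and ruditapesP_c8136 at -2.75 on replicate 1, below the next at 0.01. Marghera copper day 3 replicate 1 stood low for RP_ill_contig_38255, at -4.79 with the next at -1.29, and for RP_ill_contig_142288, at -2.73 with the next at 0.45. In the Marghera controls of day 7, RP_ill_contig_17282 stood at -1.83 on replicate 4, above the next at -2.71. Marghera copper day 1 replicate 1 had 56.0% of probes well above background, below the next at 59.2%.

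Effects that differed between the sites by a test of the difference were 5 probes for acclimation, 11 for averaged copper, and 2, 131 and 4 for copper at days 1, 3 and 7.

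The first pattern weighed is the set of 82 probes called higher after 3 days of copper in Chioggia clams, dim probes at a median level of -4.63. A trend with probe GC content as the whole cause is argued against, since the median change kept 96.0% of its size after GC centring. Slide may contribute and cannot be told apart from copper, as control and copper arrays shared no slide: the 3 copper arrays on slide 6 averaged 2.54 to 2.77 above the controls over these probes and the fourth, on slide 3 and of doubted label, 0.669, the median change went from 2.19 (median SE 0.50) to 1.03 (median SE 0.67) with slide as a fixed block, so the calls ended through a smaller change and a larger error, and Chioggia controls on slide 6 stood 0.564 above the other Chioggia controls. The background of dim probes also stays open, since 0% were called with the normexp background, a void test because other dim acclimation calls kept only 12.2%. Copper acting alike in both sites stays open as well: 13.4% of the probes were higher with copper at day 3 in Marghera clams, where the untreated controls stood 1.61 ± 0.41 (SD, n = 4) above the Chioggia controls, but probes this near the floor decide nothing, and a response to copper in Chioggia alone remains a hypothesis.

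The second pattern is the pair of Chioggia copper arrays, day 1 replicate 5 and day 3 replicate 5, each of which matched the other's column in the authors' table. An exchange of labels in 1 of the deposited sources is a candidate explanation, with correlations of at least 0.99 with the other's column against 0.010 and 0.023 with their own. The other 66 of 66 arrays matched their own column best, at 0.944 or more. No table shows which source has the pair right, and no biological explanation was tested.

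The third pattern is the set of 30 probes called at day 7 of copper in both sites. Slide as the whole cause is argued against but not excluded. The fixed block took the median change from 0.99 to 1.29 in Chioggia (131%) and from 0.97 to 1.02 in Marghera (105%). Its median SE rose from 0.23 to 0.38 and 0.31, which left 2 shared calls. No slide held both groups in either site, so the block rests on other groups. Slide 9 held all Marghera copper arrays of day 7. There they stood 0.817 above the Marghera controls of days 1 and 3, each of the 4 above each of the 3. That comparison mixes copper with day, and its copper arrays also helped choose the probes. A continued acclimation response cannot be read from direction alone, since controls of the same day were held as long and would share it. In Chioggia and Marghera 27 and 26 of the 30 probes (86.7% in the lower site) moved in the direction of the acclimation change. With slide as a fixed block 26 and 25 did. Of all tested probes 56.3% and 54.0% did. Of all probes called at day 7 it was 73.8% and 73.7%, or 77.4% and 50.0% with the block. Without copper the mean over the 30 probes did not move further that way. It was 0.02 ± 0.06 and 0.04 ± 0.16 after acclimation and -0.235 ± 0.134 and -0.181 ± 0.377 in the day 3 controls (SD, n = 4 each). The day 7 controls, which helped choose the probes, stood at -0.43 ± 0.08 and -0.44 ± 0.15 (SD, n = 4 each). A copper response already present at days 1 and 3 stays open: the mean over the 30 probes was higher with copper by 0.22 and 0.56 in Chioggia and 0.40 and 0.67 in Marghera (27, 29, 27 and 30 probes in that direction, and 22, 24, 25 and 29 under the fixed block), at adjusted p = 0.0571 for each in exact two-sided permutation tests that cannot go below 0.0286 unadjusted. A response to copper shared by the sites remains a hypothesis. It was found on the day 7 arrays, and the tests on the arrays of days 1 and 3, which did not choose the probes, did not pass.

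Other splits of the same arrays were counted with the real split included. These splits ignore slide. Among them chance can be excluded for site in wild clams (1 of 100 splits, 417 probes against at most 286 in another split) and acclimation in Marghera (1 of 100, 790 against 412). For site in controls (1 of 100, 503 against 35) arrays were regrouped within each day. So were those for averaged copper in Chioggia (1 of 100, 115 against 22) and Marghera (1 of 100, 330 against 21). Within days the sites shared only slide 10, at day 1. Copper and control shared no slide in Chioggia and only slide 7, at day 3, in Marghera. The real split was there largely a split by slide, so chance can be excluded only among splits that ignore slide. The fixed slide block called 241 probes for site in controls, and 47 and 270 for averaged copper. No slide held both groups for acclimation in Chioggia (1 of 100, 478 against 195) or for copper at day 7 in Chioggia (1 of 35, 103 against 6) and Marghera (1 of 35, 251 against 16). The real split was there also a split by slide, so the other splits cannot tell copper or acclimation from slide. At day 7 a fixed slide block called 53 and 52 probes. A fit of only the Marghera groups called 0, with 1413 in limma at an unadjusted p under 0.05. For averaged copper by site 1 of 100 splits gave as many (11 against 9), but the margin is small: leaving out 1 array gave as few as 4, leaving out the 3 dim Marghera copper arrays of day 3 gave 2, and the normexp background gave 0, with 1208 in limma at an unadjusted p under 0.05. For copper in Marghera at day 3 it can be excluded only among splits that ignore slide (1 of 35; 82 against 48), as 3 of the 4 copper arrays lay on slide 8 without a control of that day and the split with 48 kept them together, and with slide as a fixed block limma called 0, with 790 at an unadjusted p under 0.05. For the acclimation interaction 4 of 100 splits gave as many, but another split called 106 probes against the real 5. With the block limma called 0, with 1237 at an unadjusted p under 0.05. A split that called several times the real count points to a structure of the arrays, so the low share does not settle whether chance is excluded. Chance cannot be excluded for site after acclimation (6 of 35; 2 against 102), copper at day 1 in Chioggia (7 of 35; 1 against 41) and Marghera (3 of 35; 2 against 2), or copper at day 3 in Chioggia (2 of 35; 86 against 326). That split of day 3 with 326 probes set slides 3 and 5 against slides 6 and 10, and with slide as a fixed block the real value was 0 in limma, with 729 at an unadjusted p under 0.05. Structure of the arrays also shows in the other splits with many calls after acclimation and at day 1 in Chioggia, and for wild clams and Chioggia acclimation the highest split put arrays of slide 1 together, where the fixed-block values were 187 and 48.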

How the results depend on the processing

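Chosen only after the data were examined were slide as a random block, GC bins centred, the filter at 34 of 68 arrays, the percentile over probes detected on all arrays, the exchange or removal of the doubted pair, and leaving out the 3 dim Marghera copper arrays of day 3 on slide 8. The other alternatives were fixed before. Of the 51 named values, 48 kept their direction and call when the percentile was taken over probes detected on all arrays, 50 with array weights, 46 with a trended robust prior, 45 with GC bins centred, 45 of 50 with the authors' values, 42 with quantile normalization, 40 without a filter on dim probes, 33 of 34 with the filter at 34 of 68 arrays and 32 with slide as a random block. It was 26 over all fits that left out 1 array, 23 with only the groups compared, 19 with slide as a fixed block, 19 with the normexp background and 10 with the replicate number as a block. With the doubted pair exchanged, or without both arrays, 10 of 11 did, and without the 3 dim arrays 4 of 10. The calls kept under every alternative were those of RP_ill_contig_1750 and ruditapesP_c8136 for averaged copper in Chioggia, RP_ill_contig_3019 for averaged copper in Marghera, and RP_ill_contig_190621, ruditapesN_lrc32645 and ruditapesP_lrc34953_1 for site in controls.

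The normexp background called 6 probes for site in wild clams, 50 for site in controls, 0 for the acclimation interaction, 0, 0, 9 and 25 for copper in Chioggia at days 1, 3 and 7 and on average, 22, 48 and 19 for copper in Marghera at days 3 and 7 and on average, and 0 for copper by site. It turned the direction of RP_ill_contig_122132_AS for acclimation in Chioggia, to -0.10, and of RP_ill_contig_33484 for copper by site, to 0.12. Its offset of 50 exceeded the median processed signal of every array, which compresses dim probes, but input signal, correction and offset changed together and were not tested apart. In limma its 4 fits with 0 calls had 263 to 1208 probes at an unadjusted p under 0.05.

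Slide as a fixed block called 187 probes for site in wild clams, 0 after acclimation, 241 in controls, 48 for acclimation in Chioggia, 0 for the acclimation interaction, 0, 0, 53 and 47 for copper in Chioggia at days 1, 3 and 7 and on average, 0, 0 and 52 for copper in Marghera at days 1, 3 and 7, and 26 for copper by site. Its 8 counts of 0 in limma stood beside 487 to 1237 probes at an unadjusted p under 0.05, the interactions per day included. Slide as a random block called 220 for acclimation in Chioggia, 3 and 51 for copper in Chioggia at days 3 and 7, 1, 3 and 93 for copper in Marghera at days 1, 3 and 7, and 34 for copper by site.

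A fit of only the groups compared, which has fewer arrays to estimate the spread, called 73 for site in wild clams, 1 after acclimation, 324 in controls, 150 and 217 for acclimation in Chioggia and Marghera, 0 for their interaction, 0, 1, 12 and 75 for copper in Chioggia at days 1, 3 and 7 and on average, 0, 1, 0 and 146 for copper in Marghera in that order, and 19 for copper by site. In limma its 4 counts of 0 had 391 to 1413 probes at an unadjusted p under 0.05.

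Array weights called 21 for site after acclimation, 890 for acclimation in Chioggia, 334, 171 and 238 for copper in Chioggia at days 3 and 7 and on average, 252 for copper in Marghera at day 3 and 102 for copper by site. Quantile normalization called 1 for site after acclimation, 0 for the acclimation interaction (927 in limma at an unadjusted p under 0.05), 155 for copper in Marghera at day 3 and 24 for copper by site. The authors' values called 1 for site after acclimation, 4 for copper in Chioggia at day 1 and 4 for copper by site. GC bins centred called 0 for site after acclimation (710 in limma at an unadjusted p under 0.05) and 2 for the acclimation interaction. No filter on dim probes called 2372 for acclimation in Marghera, 0 for the acclimation interaction (1254 in limma at an unadjusted p under 0.05), and 2 and 170 for copper in Chioggia at days 1 and 3. The filter at 34 of 68 arrays, which tests fewer probes, called 1 for copper in Chioggia at day 3, 1 for copper in Marghera at day 1 and 7 for copper by site. The percentile over probes detected on all arrays called 128 for copper in Marghera at day 3 and 45 for copper by site, and it shifted the median of all probes by over 0.1 in 3 comparisons, at most by -0.11. With the doubted pair exchanged 205 were called for copper in Chioggia at day 3 and 23 for copper by site, and without both arrays 292 and 64. Without the 3 dim arrays 6 were called for copper in Marghera at day 3, 100 on average and 2 for copper by site, and the day 3 changes of RP_ill_contig_38255 and RP_ill_contig_142288 turned to -0.089 and -0.17, where the lone array left is assumed to vary like the other groups. Apart from the fits on fewer arrays or probes, the cause of these moves was not tested.

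With 1 array left out in turn, the count ran from 116 to 567 for site in wild clams, from 0 to 6 after acclimation and from 333 to 567 in controls. It ran from 271 to 483 for acclimation in Chioggia, from 450 to 865 in Marghera and from 0 to 4 for their interaction. For copper in Chioggia it ran from 1 to 4 at day 1, from 10 to 284 at day 3, from 58 to 107 at day 7 and from 88 to 208 on average. For copper in Marghera it ran from 1 to 9, from 2 to 216, from 120 to 269 and from 197 to 482 in that order, and for copper by site from 4 to 93. The arrays behind each move over 1.5 times are named beside the counts in the report. In limma the 15 such fits with 0 calls had 505 to 1185 probes at an unadjusted p under 0.05.

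The replicate number as a block called 10 for site in wild clams, 0 after acclimation, 147 in controls, 0 and 0 for acclimation in Chioggia and Marghera, 0 for their interaction, 0, 0, 0 and 28 for copper in Chioggia at days 1, 3 and 7 and on average, and 0, 1, 0 and 24 for copper in Marghera in that order. In limma these 9 counts of 0 had 415 to 2036 probes at an unadjusted p under 0.05. The numbers do not pair the arrays: same-numbered arrays correlated from -0.221 to 0.309, in no comparison was every pair over 0.1, and in no comparison was every array closest to its own number. The block therefore removes degrees of freedom without a known shared source.

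The gene lists fixed before the data were examined, and their alternatives, were not run, since 0 of their 238 symbols stood among the probe names. Signal over background limits the rest: 10727 of 15037 probes were well above background on at least 4 arrays, and for probes near that limit the size of a change is a bound or rests on few arrays.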

Other observations

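All tests in this part were chosen only after the result was seen.

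The 168 probes that changed on acclimation in both sites were followed into the exposure period as a mean deviation signed by the acclimation change. In Chioggia clams it was -0.76 ± 0.17 in wild clams (SD, n = 6), 0.25 ± 0.04 after acclimation and 0.18 ± 0.08, 0.08 ± 0.06 and -0.07 ± 0.10 in the controls of days 1, 3 and 7 (SD, n = 4 each). In Marghera clams it was -0.68 ± 0.12 in wild clams (SD, n = 6), 0.31 ± 0.06 after acclimation and 0.18 ± 0.02, 0.08 ± 0.18 and -0.25 ± 0.04 in the controls (SD, n = 4 each). The day 7 copper arrays stood at 0.31 ± 0.05 in Chioggia and 0.17 ± 0.08 in Marghera (SD, n = 4 each). Between the end of acclimation and the day 7 controls 32 probes differed in Chioggia (14 higher, 18 lower) and 582 in Marghera (273 higher, 309 lower), with 9 higher and 6 lower in both and 0 in opposite directions. The counts were 167 and 291 with slide as a fixed block.

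A hypothesis is that the acclimation change reverses during longer holding. At day 7 the controls stood 68.6% of the way from wild to acclimated in Chioggia and 43.4% in Marghera. The probes were chosen for their high acclimated level, which would bring later values back towards the mean. Slide apart, that choice gives no further fall among the controls, which had no part in it. They fell from 0.18 ± 0.08 at day 1 to -0.07 ± 0.10 at day 7 in Chioggia (SD, n = 4 each). In Marghera they fell from 0.18 ± 0.02 to -0.25 ± 0.04 (SD, n = 4 each). Slide apart, these values argue against the choice of probes as the whole cause. The Chioggia controls lay on slides 2 and 10 at day 1 and on slide 6 at day 7, so their fall cannot be told apart from slide. The move to aquaria without sediment came at the same time, so reversal cannot be told apart from that move.

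Another hypothesis is that copper held these probes at the acclimated level. At day 7 the copper arrays stood above the controls by 0.38 in Chioggia and 0.42 in Marghera, with 4 of 4 copper arrays above all controls in each site and 149 and 150 of 168 probes in that direction. Under the fixed slide block the differences were 0.29 and 0.38, with 118 and 134 probes. The exact two-sided permutation p at day 7 was 0.0286 in each site, the smallest 4 against 4 arrays can give, and the adjusted p over 6 tests was 0.0857, so the test does not pass and cannot decide. The differences at days 1 and 3 were 0.06 and 0.10 in Chioggia (adjusted p = 0.446 and 0.171 in the same permutation test, with 1 and 3 copper arrays above all controls) and 0.02 and 0.24 in Marghera (0.686 and 0.171, with 1 array each). RP_ill_contig_3019 went the same way in each case, lower on acclimation and lower with copper.

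A difference between sites kept through acclimation is a further hypothesis, since only 2 probes were called after acclimation. Of the 42 probes called in the same direction in wild clams and in controls, 41 (97.6%) had that direction on the acclimated arrays, which were not used to choose them, at a median log2 difference of 0.80 against 1.41 in wild clams and 0.87 in controls. With slide as a fixed block 42 did. Of all 417 probes called in wild clams, 66.7% had the same direction on the acclimated arrays (71.7% of 187 with the block) and 48.0% in the controls (72.7% with the block), so the 42 do not stand for the rest. Probes share arrays and are not independent, so these shares carry no p.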
